A study of Rattus norvegicus with 19 samples.

How the data were processed

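The series holds 19 RNA sequencing libraries from primary cultures of the ventral spinal cord of Sprague-Dawley rat embryos. The labels put 5 libraries in the untreated group (control), 5 in the group given long-chain synthetic polyphosphate (polyP) at 100 μM, 4 in the group given medium conditioned by mouse astrocytes that carry human wild-type SOD1 (wtSOD1-ACM) and 5 in the group given medium conditioned by mouse astrocytes that carry human SOD1 with the G93A change (mutSOD1-ACM). Exposure to polyP or conditioned medium lasted 90 min. Per the labels' protocols, RNA came from 4 to 5 independent cultures per condition, while the series text speaks of quadruplicates. Libraries are treated here as separate cultures on the strength of the labels, and this was not tested. The labels give the age of the cultures as 7 days in vitro in the tissue field and 4 days in vitro in the treatment protocol, and the growth protocol gives a wider range, so the age stays open here. The libraries were made with a poly(A)-enriching TruSeq protocol, and the series design describes the reads as strand-specific.

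The values are FPKM (fragments per kilobase of transcript and per 1e+06 fragments) per gene and library, deposited by the authors in a single table with 2 decimals, per the file headers. Per the submitters' processing notes, reads were aligned with HISAT to the rat genome build rn6. The version of the aligner, the tool that made the FPKM, the gene annotation release and any scaling between libraries are not given in the sources used here. The table holds 15597 genes, each with a symbol and a numeric gene identifier, and all 19 sample columns were matched to a library by name. The reference annotation at hand belongs to another rat assembly (GRCr8), so it was used for names only, and no genomic position or gene length is reported. FPKM are not counts, so no count model was fitted. Because lengths enter the unit, a shift of fragments towards shorter transcripts raises the sum of all FPKM in a library.

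Total fragment numbers are not part of the table, but relative depth was recovered from 225 rarely detected genes. Their 1287 values lay at whole multiples of 1 fragment, within 0.1 fragment, in 91.4% of cases. The fragment unit of each gene was set from its own smallest value, which matches by construction. The depths were fitted to these same genes, so this share describes the fit and is not a test of it. Relative to the median library, depth ran from 0.762 to 1.35, a ratio of 1.78. The absolute depth stays unknown, so no counting interval is given, and low FPKM carry more counting error than high FPKM to an extent that is not known.

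Tests were run in R 4.3.3 with limma 3.58.1 and statmod 1.5.0 on log2(FPKM + 1). A gene was tested when it reached an FPKM of 1 in at least 4 of the 19 libraries, which left 11887 genes. All 4 groups entered a single fit with the group as the only term, followed by empirical Bayes moderation with a trend and robust estimation. P-values are two-sided, adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p under 0.05. Log2 fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. Every adjusted p of a gene in the text is from limma. Means are given ± SD of the FPKM over the libraries of a group.

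Gene lists were written before the data were examined, from textbook knowledge. Of 45 lists, 43 had at least 5 tested members, and 778 of their 895 entries were tested. Lists were tested with limma's camera with a preset correlation between genes of 0.01 and, as an alternative, with an estimated correlation, each adjusted over the lists of a comparison. Calls of list members are given over all genes and adjusted over the list alone. The text names, per comparison, the genes with the largest rises and falls among called genes whose libraries all lay on 1 side of the mean of the compared group (at most 10 each way), the members of each described list with the smallest p (at most 4), the shared genes with the largest smaller change (at most 10), and Fos, Npas4, Bdnf, Sod1, Gfap and Chat whatever their result. Where fewer than 3 genes passed, the 5 with the smallest p are named. Symbols that are only identifiers are counted and not named, and some genes that the rule names are not reported here. The rule and the comparisons were fixed at the same time as the lists, and a gene outside the rule is said to be chosen after its values were seen.

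Clustering of the libraries showed 2 sets, of 11 and 8 libraries, that cut across all 4 groups. This was found after the data were examined, the labels give no batch, and the sets are not groups of the study. Set 1 holds 3 control, 3 polyP, 2 wtSOD1-ACM and 3 mutSOD1-ACM libraries, and set 2 holds 2 of each group. The sets follow the replicate numbers, with the lower numbers of each group in set 1 and the last 2 in set 2. Values within each set are given beside the pooled values, and a fit with the set as a term was added. Other alternatives were pseudocounts of 0.1 and 0.5, no filter on low values, a filter at a mean FPKM of 5, median-of-ratios scaling, quantile normalization, moderation without a trend, array weights, the replicate number as a block, a fit of the compared groups only, and leaving out each library. Chosen after seeing the data were the terms for 2 or 3 library sets, each set alone, scaling to equal summed FPKM, the set term without control replicate 2, and the set term with median-of-ratios scaling.

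Overlaps of calls were tested with a one-sided Fisher's exact test, adjusted over a family of 20. For comparisons that share the control libraries, 100 simulated data sets with no effect were drawn by resampling residuals within library sets, and 100 more, chosen after seeing the data, with the effects of 3 library classes kept. The procedure was tested on simulated data for 11887 genes with 200 changed genes. With the library sets in the spread and no set term, the simulated polyP comparison recovered 55% of changes of 1.5-fold and 89% of changes of 2-fold, with 0 false calls. The simulated comparison of mutSOD1-ACM with wtSOD1-ACM recovered 59% and 88%, with 4 false calls. With the set term the shares were 78% and 96% for polyP and 76% and 96% for the conditioned media, with 8 and 9 false calls. In simulations without library sets and with no set term, 8.02% of polyP calls and 8.51% of conditioned medium calls were false. The simulated noise was independent between genes and held no effect of the 3 library classes. The numbers of false calls therefore need not hold for the real libraries. Single values such as summed FPKM were compared with exact two-sided permutation tests (Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1), and plots were drawn with matplotlib 3.10.9.

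Several named genes need care. Ribosomal protein genes, Hmgb2 and the pseudogene Ybx1-ps3 have near-identical copies elsewhere in the genome with which reads may be shared, and how such reads were assigned is not stated. Mir138-2, Mir760 and Mir1896 are precursors of short RNAs that a poly(A) library measures poorly and that lie within or near longer transcripts, so their values are uncertain.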

Results

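The data are gene expression levels (FPKM) in 19 cultures of rat embryonic ventral spinal cord, which hold neurons and glia. The cultures were untreated (control, n = 5), given long-chain polyphosphate at 100 μM for 90 min (polyP, n = 5), or given for 90 min medium conditioned by astrocytes expressing wild-type human SOD1 (wtSOD1-ACM, n = 4) or SOD1 with the G93A change (mutSOD1-ACM, n = 5). Polyphosphate is a linear polymer of phosphate, and SOD1 is a superoxide dismutase whose mutations, G93A among them, cause a familial form of amyotrophic lateral sclerosis (ALS). The series title asks which transcripts polyP and mutSOD1-ACM induce in common. The number of genes at an FPKM of 1 or more ran from 11309 to 11723 per library, and relative depth ran from 0.762 to 1.35 of the median library. Within groups, Pearson's r of log2 values across genes lay between 0.956 and 0.997.

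The libraries fell into 2 sets that cut across the treatments, a division found after the data were examined. In set 1 (11 libraries) Mbp, the gene of myelin basic protein, stood at 169 to 372 FPKM, and in set 2 (8 libraries) at 6.54 to 9.62 FPKM. The gene of another myelin protein, Mag, went the same way, at 18.0 ± 6.95 (SD, n = 11) against 0.285 ± 0.090 FPKM (n = 8, adjusted p from limma 3.59e-11). The sets were clustered from these same values, so this p and the counts of markers describe the sets and are not a test. Of 16 tested markers of the oligodendrocyte lineage 14 were higher in set 1, and all 17 markers of microglia and macrophages were higher, with C1qa at 33.4 ± 21.7 against 5.76 ± 1.07 FPKM. Of 8 motor neuron markers 7 were lower in set 1. Ribosomal RNA made up 0.958% to 2.09% of the summed FPKM in set 1 and 0.166% to 0.410% in set 2. Each treatment was present in both sets, and the first principal component, with 43.05% of the variance, separated them. Genes outside the naming rule in this paragraph were chosen after their values were seen.

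**Figure D1:**
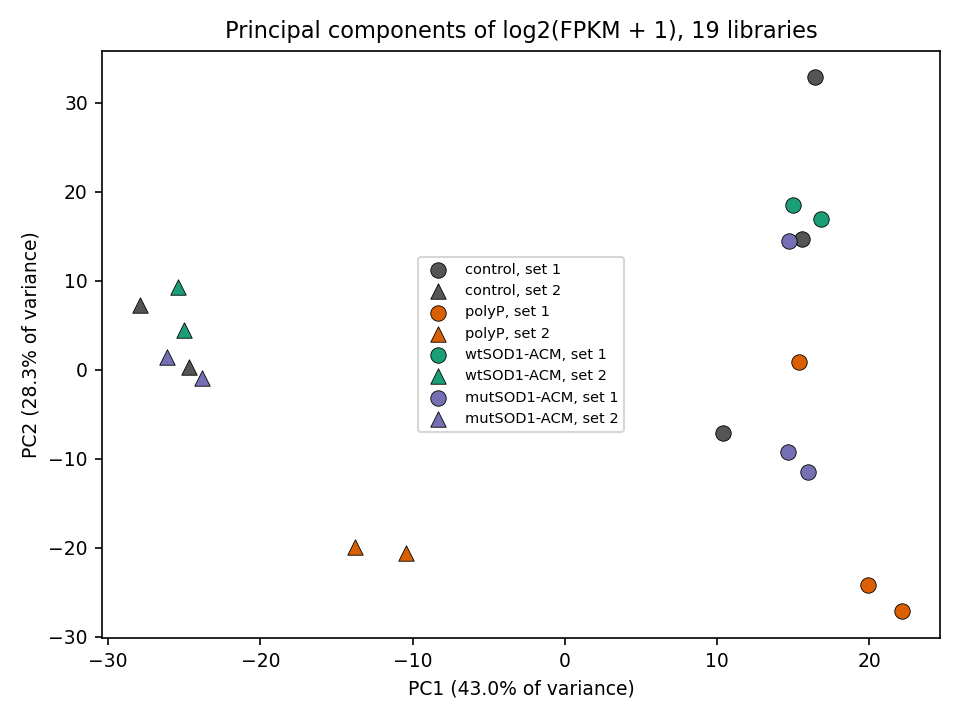
Principal components of log2(FPKM + 1) for the 19 libraries, with the first component (43.05% of variance) on the horizontal and the second (28.34%) on the vertical axis; colours give the 4 groups, circles library set 1 and triangles library set 2. Set 1 lies between 10.4 and 22.1 and set 2 between -27.9 and -10.45 on the first component.

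The first comparison asked what polyP changed relative to untreated cultures. Immediate early and activity-regulated genes were among the largest falls. Egr1 (identifier 24330), a zinc-finger transcription factor induced within minutes by growth factors and synaptic activity, dropped from 72.9 ± 16.1 to 25.9 ± 4.77 FPKM (SD, n = 5 each; log2 fold change -1.45, limma adjusted p = 1.93e-05). Ptgs2 (29527), the inducible cyclooxygenase, dropped from 29.1 ± 3.63 to 9.41 ± 1.91 FPKM (-1.54, limma adjusted p = 8.49e-07), and Egr2 (114090) from 22.0 ± 3.79 to 8.17 ± 1.68 FPKM (-1.33). The largest rise on the log2(FPKM + 1) scale, apart from 1 gene whose symbol is only an identifier, was that of Fabp7 (80841), a brain lipid-binding protein of radial glia, from 983 ± 177 to 1899 ± 207 FPKM (0.96, limma adjusted p = 1.23e-04). For each of these 4 genes the 5 polyP values did not overlap the 5 control values.

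Other large falls were these. Flnc (362332), the actin cross-linker filamin C, fell from 184 ± 40.1 to 59.5 ± 19.9 FPKM (-1.63), and Thbs1 (445442), the matrix glycoprotein thrombospondin 1, from 1176 ± 264 to 404 ± 130 FPKM (-1.57). Epha2, a receptor tyrosine kinase for ephrins, fell by 1.41 on the log2 scale, and Plaur, the urokinase receptor, by 1.32. The cytokines of the interleukin-6 family Lif and Clcf1 fell by 1.43 and 1.61, with Lif going from 11.6 ± 3.63 to 3.70 ± 1.52 FPKM. Limma adjusted p of these genes lay between 6.47e-05 and 0.00126. Among the rises, Hmgb2, a chromatin protein of dividing cells, went from 143 ± 15.0 to 250.5 ± 27.2 FPKM (0.81), and Pclaf, a PCNA-binding factor, from 34.5 ± 6.61 to 58.2 ± 7.31 FPKM (0.75). Psat1, an enzyme of serine synthesis, rose from 68.0 ± 11.4 to 114 ± 14.5 FPKM (0.74), Ddit4, a stress-induced inhibitor of mTORC1 signalling, from 28.8 ± 4.38 to 48.2 ± 4.38 FPKM (0.73), and Olig1, a transcription factor of the oligodendrocyte lineage, from 80.6 ± 22.2 to 137 ± 23.9 FPKM (0.78, limma adjusted p = 0.0131). Lower-expressed rises were those of Foxb1 (0.79), Meox2 (0.78) and Ddit4l2 (0.79), and the pseudogene Ybx1-ps3 (0.75) and the short RNA precursor Mir138-2 (-1.52) are uncertain.

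Not every gene induced by activity moved. Fos stood at 123 ± 31.5 in control and 121 ± 36.1 FPKM with polyP (-0.04, limma adjusted p = 0.92). Npas4 (26.6 ± 9.85 and 24.5 ± 12.4 FPKM, adjusted p = 0.782) and Bdnf (9.75 ± 1.77 and 8.79 ± 1.21 FPKM, adjusted p = 0.414) did not pass the limma test. Sod1 rose from 204 ± 26.9 to 249 ± 25.3 FPKM (0.29, limma adjusted p = 0.0265), a call that ended without 1 library in 5 of the 19 cases, with an adjusted p of up to 0.0798 without control replicate 2. The astrocyte gene Gfap stood at 22.4 ± 8.64 and 19.3 ± 6.19 FPKM (limma adjusted p = 0.591). Chat, the marker enzyme of cholinergic neurons, was not tested, with an FPKM of at most 1.34.

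**Figure D2:**
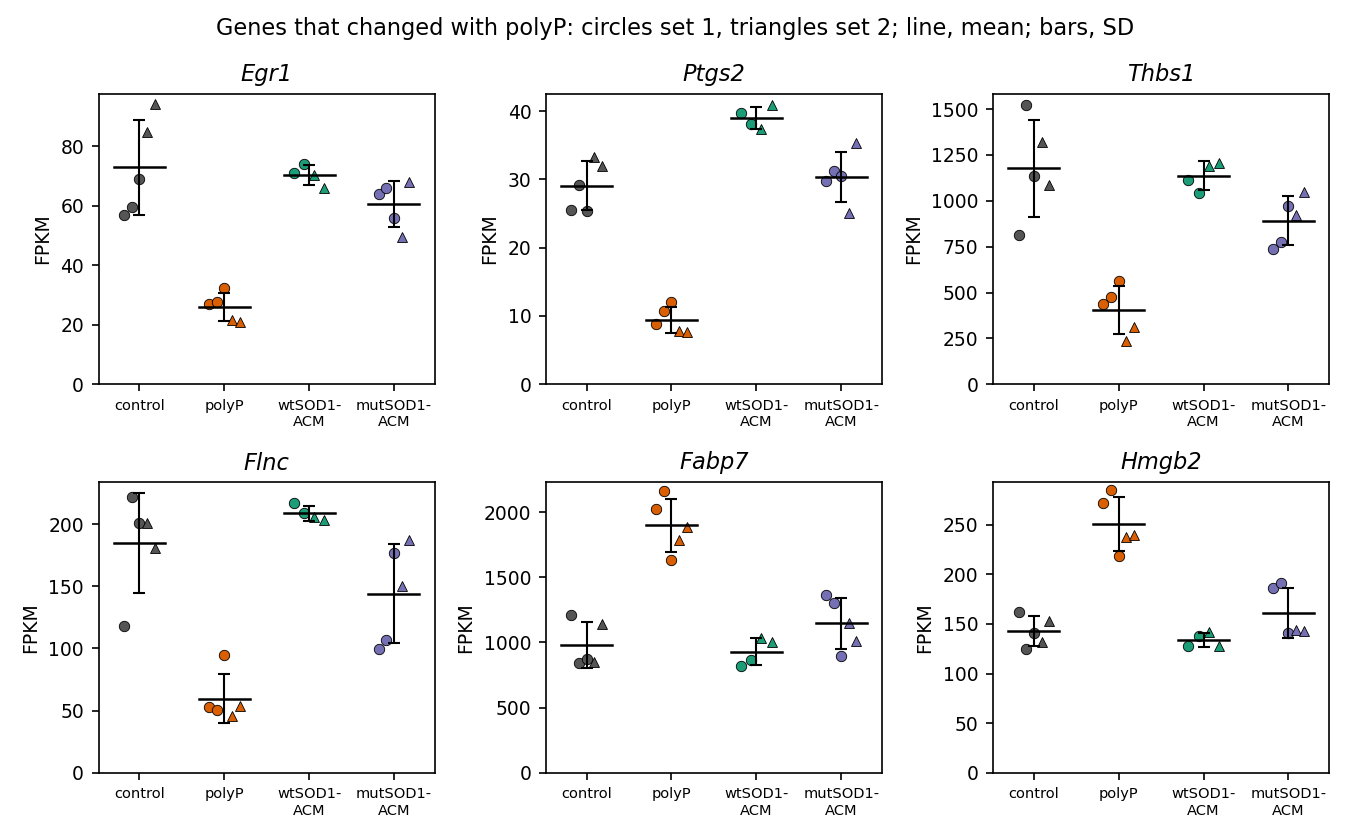
FPKM of 6 genes in the 4 groups, each library a point (circles, set 1; triangles, set 2), with the group mean as a line and the SD as bars on a linear axis from 0. Egr1, Ptgs2, Thbs1 and Flnc were lower, and Fabp7 and Hmgb2 higher, with polyP than in control, as in Ptgs2 with 9.41 ± 1.91 against 29.1 ± 3.63 FPKM.

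Members of several gene lists fixed beforehand fell, although the lists did not pass camera with an estimated correlation. Of 35 tested rapid immediate early genes 17 fell and 0 rose, with Trib1 (-0.71) and Fosl1 (-0.79) after Egr1 and Egr2 (17 adjusted over the list alone; camera adjusted p = 9.17e-10, adjusted p = 0.19 with an estimated correlation). Of 26 delayed activity-regulated genes 9 fell and 1 rose, with Ptgs2, the secreted neuropeptide precursor Vgf (-0.88), the receptor Gpr3 (-0.53) and the kinase Pim1 (-0.51) falling (9 and 1 adjusted over the list alone; camera adjusted p = 5.55e-05, adjusted p = 0.223 with an estimated correlation). Of 21 MAPK and MYC feedback genes 10 fell and 2 rose (10 and 4 adjusted over the list alone). The growth factor Hbegf (-1.25), the phosphatase Dusp2 (-0.64) and Phlda1 (-0.57) fell and the ETS factor Etv5 (0.45) rose (camera adjusted p = 0.00307, adjusted p = 0.19 with an estimated correlation). Of 18 TGF-beta and BMP targets 9 fell, also 9 adjusted over the list alone, among them the matrix protein Ctgf (-0.69), Ltbp2 (-0.92) and the transcriptional inhibitor Id3 (-0.58). That list had a camera adjusted p of 8.36e-05, and an adjusted p = 0.19 with an estimated correlation.

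Members of 4 lists of ion channel and receptor genes fell. Of 24 calcium channel and calcium handling genes 16 fell, also 16 adjusted over the list alone, with the sarco/endoplasmic calcium pump Atp2a2 (-0.54), the plasma membrane pump Atp2b1 (-0.50), the L-type channel subunit Cacna1c (-0.55) and the ryanodine receptor Ryr2 (-0.48; camera adjusted p = 6.07e-08, adjusted p = 0.19 with an estimated correlation). Of 22 glutamate receptor genes 6 fell (4 adjusted over the list alone), with the NMDA receptor subunit Grin1 going from 55.4 ± 8.55 to 33.3 ± 4.15 FPKM (-0.71), and with Gria2 (-0.45), Grik2 (-0.30) and Gria3 (-0.48). The list had a camera adjusted p of 3.45e-05 and an adjusted p = 0.19 with an estimated correlation, and the call of Gria3 ended without control replicate 4 (limma adjusted p = 0.0507). Of 10 sodium channel subunits 6 fell (Scn8a -0.50, Scn2a -0.36, Scn3a -0.39; 6 adjusted over the list alone; camera adjusted p = 0.000158, adjusted p = 0.19 with an estimated correlation). Of 32 potassium channel subunits 5 fell (Kcnj4 -0.61, Kcnk3 -0.33, Kcna6 -0.33; 4 adjusted over the list alone; camera adjusted p = 0.000269, adjusted p = 0.238 with an estimated correlation). Of 19 GABA and glycine receptor genes 3 fell and 2 rose (2 and 2 adjusted over the list alone), with a median of 0.06 while camera pointed down and did not pass (adjusted p = 0.215, adjusted p = 0.679 with an estimated correlation). Of 8 motor neuron markers 2 fell (3 adjusted over the list alone; camera adjusted p = 0.0237, adjusted p = 0.479 with an estimated correlation), and of 13 inhibitory neuron markers 2 fell, also 2 adjusted over the list alone (camera adjusted p = 0.0361, adjusted p = 0.48 with an estimated correlation). By contrast, of 17 pan-neuronal markers 1 rose and 0 fell, with a median of 0.11 (camera adjusted p = 0.746, adjusted p = 0.902 with an estimated correlation).

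Of 19 endoplasmic reticulum chaperone genes 8 fell (9 adjusted over the list alone), with Hspa5, the main Hsp70 of that compartment, going from 507 ± 52.7 to 365 ± 45.0 FPKM (-0.47), beside Hyou1 (-0.62), Hsp90b1 (-0.46) and Pdia4 (-0.42). The list had a camera adjusted p of 7.12e-05 and an adjusted p = 0.273 with an estimated correlation. Of 25 NF-kB inflammatory targets 5 fell and 1 rose (4 and 1 adjusted over the list alone), the falls including the adhesion molecule Icam1 (-0.74), Tnfaip2 (-0.70), Nfkbiz (-0.50) and the chemokine Cx3cl1 (-0.49; camera adjusted p = 0.00775, adjusted p = 0.48 with an estimated correlation). The median of this list was -0.25 in set 1 and 0.00 in set 2. Of 17 microglia and macrophage markers 0 passed the limma test either over all genes or adjusted over the list alone, with a median of -1.15 in set 1 and 0.04 in set 2 (camera adjusted p = 0.0133, adjusted p = 0.612 with an estimated correlation). Set 1 itself held 2 classes of libraries, with Mbp at 169 to 216 and Cx3cr1 at 3.20 to 6.51 FPKM in 1 of them, and Mbp at 292 to 372 and Cx3cr1 at 11.2 to 32.8 FPKM in the other. The former held control replicate 1 and polyP replicates 1 and 2, the latter control replicates 2 and 3 and polyP replicate 3, so the median in set 1 mixes treatment with class. Within the classes it was -0.43 and -1.04, from 3 libraries each. The values of the list include Cx3cr1 at 13.1 ± 12.4 and 5.23 ± 3.47 FPKM (-0.90, limma adjusted p = 0.209).

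All 40 tested cytosolic ribosomal protein genes rose, also 40 adjusted over the list alone, with Rpl3 going from 628 ± 22.8 to 813 ± 31.5 FPKM (0.37) and with Rpl4 (0.48), Rpl22 (0.44) and Rps20 (0.56; camera adjusted p = 2.48e-18, adjusted p = 0.238 with an estimated correlation). The list median was 0.37 in set 1 and 0.44 in set 2. Of 23 proliferation genes 17 rose (19 adjusted over the list alone), with the replication clamp Pcna going from 112 ± 10.5 to 174 ± 13.1 FPKM (0.63), beside Ccnb1 (0.36), Mcm6 (0.38) and Mcm2 (0.35; camera adjusted p = 1.29e-06, adjusted p = 0.273 with an estimated correlation). Of 33 nuclear-encoded respiratory chain genes 16 rose (18 adjusted over the list alone), among them Uqcrfs1 (0.41), Sdhc (0.36), Ndufb5 (0.34) and Ndufv2 (0.30; camera adjusted p = 6e-04, adjusted p = 0.48 with an estimated correlation). Of 17 heat shock genes 10 rose and 2 fell, also 10 and 2 adjusted over the list alone, with the mitochondrial chaperonin Hspd1 (0.40) and the Hsp90 activator Ahsa1 (0.33) higher and the co-chaperone Bag3 (-0.50) lower (camera adjusted p = 0.0315, adjusted p = 0.48 with an estimated correlation). Hsp90ab1 rose by 0.24 but stood at -0.05 after quantile normalization.

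In all, 3779 of 11887 genes passed the limma test with polyP, 2736 higher and 1043 lower, with a median log2 change of 0.31 among the higher and -0.40 among the lower. On the log2(FPKM + 1) scale, only 1 gene rose and 24 fell by 2-fold or more. By mean FPKM some called genes with low values rose by more, such as Meox2 from 0.652 to 1.83 and Ddit4l2 from 0.842 to 2.12. Set 1 alone gave 1819 higher and 651 lower, set 2 alone 3336 and 2144, and the fit with the set as a term 3886 and 2308, and all 3779 genes had the same sign in both sets and stayed called with the set term. The genes were called on the libraries of both sets together. Their agreement in sign between the sets is thus largely given by selection, here and in the comparisons below. The split of calls depended on scaling. With FPKM as deposited 72.4% of calls were higher, with median-of-ratios scaling 53.7% (1793 higher, 1545 lower) with equal summed FPKM 45.7% (1404 higher, 1667 lower), and after quantile normalization 67.7% (2320 higher, 1105 lower). Equal summed FPKM moved the median of all genes by -0.10. The summed FPKM was 502340 ± 12154 with polyP and 464190 ± 13827 in control (ratio 1.08, exact two-sided permutation p = 0.0079, the smallest possible for 5 against 5). No gene lengths were at hand, so a dependence of the changes on transcript length was not tested. None of the scalings uses lengths, so none would remove such a dependence from the ribosomal protein, channel or other lists. Of 43 lists 22 passed camera, 0 of them with an estimated correlation. With equal summed FPKM the median was 0.29 for the ribosomal protein genes (39 called; 0.13 and 23 after quantile normalization), 0.25 for proliferation genes (13), 0.08 for respiratory chain genes (8) and 0.12 for heat shock genes (6). The medians of the rapid immediate early genes and of the calcium genes were then -0.42 and -0.58.

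The second comparison set medium of mutant SOD1 astrocytes against medium of wild-type SOD1 astrocytes. Chemokines and other NF-kB targets were far lower with the mutant than with the wild-type medium. Falls and rises in this comparison are relative to the wild-type medium and not to untreated cultures. Ccl2 (identifier 24770), a monocyte attractant, stood at 4.02 ± 1.93 FPKM with mutSOD1-ACM (n = 5) and 134 ± 37.4 FPKM with wtSOD1-ACM (n = 4; log2 fold change -4.78, limma adjusted p = 4.8e-08; -4.98 in set 1 and -4.65 in set 2), against 4.28 ± 2.37 FPKM in control and 3.02 ± 1.24 FPKM with polyP. Cxcl1 (81503), a neutrophil attractant, stood at 2.58 ± 0.72 and 91.6 ± 21.5 FPKM (-4.69, limma adjusted p = 1.39e-12), against 2.82 ± 0.41 FPKM in control. Icam1 (25464) stood at 15.5 ± 1.45 and 90.6 ± 11.8 FPKM (-2.47, limma adjusted p = 5.16e-08), against 19.0 ± 6.23 FPKM in control. Klf2 (306330), a transcription factor that counters inflammatory genes, was the only gene higher with the mutant medium, at 13.1 ± 1.62 against 7.82 ± 0.78 FPKM (0.67, limma adjusted p = 0.00886) and 11.5 ± 2.45 FPKM in control.

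Further chemokines fell by 2.52 (Ccl20), 2.14 (Ccl7), 1.84 (Cxcl2) and 1.74 (Cxcl3) on the log2 scale. Gbp5, a guanylate-binding protein, fell by 2.12, Birc3, an inhibitor of apoptosis, by 2.00, and Nfkbiz, a nuclear IkB protein, by 1.86, from 11.8 ± 1.98 to 2.49 ± 0.28 FPKM. Limma adjusted p of these genes lay between 6.17e-08 and 0.00114. Of the 25 NF-kB targets 17 fell (22 adjusted over the list alone; camera adjusted p = 8.96e-89, adjusted p = 0.000243 with an estimated correlation), with a median of -1.75 in set 1 and -1.23 in set 2. Of 16 STAT3 cytokine targets 4 fell (9 adjusted over the list alone), with Stat3 itself going from 65.9 ± 2.26 to 49.3 ± 1.68 FPKM (-0.41), beside Lif (-1.66), Cebpd (-1.67) and Cish (-0.60; camera adjusted p = 3.15e-18, adjusted p = 0.00101 with an estimated correlation). Of 35 rapid immediate early genes 5 fell and 1, Klf2, rose (7 and 1 adjusted over the list alone), with Ier3 (-0.72), Maff (-0.54) and Fosl1 (-0.74; camera adjusted p = 2.92e-08, adjusted p = 0.289 with an estimated correlation). Of 22 targets of the integrated stress response and ATF4, 0 passed the limma test over all genes or over the list alone. Their median was 0.13 (camera adjusted p = 1.07e-05, adjusted p = 0.00179 with an estimated correlation), with Asns at 0.15, Mthfd2 at 0.15, Sesn2 at 0.34 and Ddit4 at 0.27.

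Fos (128 ± 38.7 and 131 ± 48.2 FPKM), Npas4 (25.2 ± 12.6 and 26.5 ± 19.6), Bdnf (9.25 ± 1.09 and 8.53 ± 1.11), Sod1 (223 ± 18.1 and 208 ± 21.04) and Gfap (20.4 ± 3.95 and 33.4 ± 10.4) did not pass the limma test between the mutant and the wild-type medium (adjusted p between 0.768 and 0.998). With the set as a term Gfap did pass (-0.71, adjusted p = 0.0446), and its adjusted p ran from 0.00079 with array weights to 1 over all alternatives. In all, 56 of 11887 genes passed, 1 higher and 55 lower, and 599 had an unadjusted p under 0.05. Set 1 alone gave 2 higher and 43 lower and set 2 alone 5 and 69, and all 56 genes kept their sign in both sets. The calls were 7 higher and 92 lower with the set as a term, 1 and 32 among genes with a mean FPKM of at least 5, where fewer genes are tested, and 1284 and 1063 with array weights. Within set 1 the class with less Mbp held 2 mutSOD1-ACM libraries, and the other class held 1 mutSOD1-ACM and 2 wtSOD1-ACM libraries. Neither the set term nor array weights takes up this difference, so calls between the media, that of Gfap included, can mix medium with class. Set 2 alone is free of this difference.

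The third comparison set wtSOD1-ACM against untreated cultures. Inflammatory genes rose, with Ccl2 at 134 ± 37.4 against 4.28 ± 2.37 FPKM (log2 fold change 4.74, limma adjusted p = 5.56e-08). Cxcl1 rose by 4.58 (limma adjusted p = 2.1e-12), Icam1 by 2.23, and Nfkbia, the gene of the NF-kB inhibitor IkB-alpha, from 16.5 ± 2.50 to 53.6 ± 12.1 FPKM. Pgf, placental growth factor, rose from 3.73 ± 0.67 to 13.9 ± 0.90 FPKM (1.67, limma adjusted p = 1.61e-07). Ccl20 (2.38), Ccl7 (2.20), Birc3 (1.84), Cxcl2 (1.81), Gbp5 (1.80) and Nfkbiz (1.77) rose as well. The falls were those of Chac1, a glutathione-degrading enzyme induced by ATF4, from 50.3 ± 5.29 to 30.5 ± 4.32 FPKM (-0.71, limma adjusted p = 0.00146), Sesn2 (-0.67), Trib3 (-0.62), Herpud1 (-0.39), Mthfd2 (-0.39) and the asparagine synthetase Asns (-0.26), with the uncertain precursors Mir760 (-1.37) and Mir1896 (-0.94). Without 1 library the calls of Sesn2 (limma adjusted p = 0.0512 without wtSOD1-ACM replicate 3), Trib3 (up to 0.0742), Mir760 (up to 0.141) and Mir1896 (up to 0.126) ended.

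As groups, 16 of 25 NF-kB targets rose with wtSOD1-ACM (22 adjusted over the list alone; camera adjusted p = 6.36e-105, adjusted p = 4.44e-05 with an estimated correlation), with a median of 1.65 in set 1 and 1.17 in set 2. Of 16 STAT3 targets 5 rose (10 adjusted over the list alone), Stat3 from 48.7 ± 1.26 to 65.9 ± 2.26 FPKM (0.43), Lif by 1.61, Cebpd by 1.45 and Socs2 by 0.61 (camera adjusted p = 1.01e-19, adjusted p = 0.000465 with an estimated correlation). Of 22 targets of the integrated stress response and ATF4, 5 fell (10 adjusted over the list alone), Chac1, Mthfd2, Asns and Sesn2 with the smallest p (camera adjusted p = 2.62e-24, adjusted p = 6.2e-07 with an estimated correlation). Of 35 rapid immediate early genes 5 rose (5 higher and 1 lower adjusted over the list alone), with Gadd45b (0.77), Ier3 (1.00), Maff (0.54) and Fosl1 (0.57; camera adjusted p = 8.23e-07, adjusted p = 0.31 with an estimated correlation). Of 18 TGF-beta and BMP targets 3 rose (4 adjusted over the list alone), namely Smad7 (0.77), Pmepa1 (0.78) and Tgif1 (0.39; camera adjusted p = 0.0105, adjusted p = 0.31 with an estimated correlation). The calls of Fosl1, Socs2 and Tgif1 each ended without at least 4 single libraries (limma adjusted p of up to 0.085, 0.0764 and 0.104). The values of the genes given in every comparison were -0.26 to 0.58 for Npas4, Bdnf, Sod1, Fos and Gfap, none past the limma test.

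In all, 75 genes passed with wtSOD1-ACM, 67 higher and 8 lower, 442 had an unadjusted p under 0.05, and 25 rose by 2-fold or more on the log2(FPKM + 1) scale. Set 1 alone gave 52 higher and 3 lower and set 2 alone 82 and 11, and all 75 kept their sign in both sets. The calls were 126 higher and 17 lower with the set as a term and 172 and 42 with array weights. Within set 1 the wtSOD1-ACM libraries all lay in the class with more Mbp, while control replicate 1 did not. Calls outside set 2 alone can thus mix medium with class here as well. A fit of the 2 groups alone, with fewer libraries, gave 32 and 1, and of the 8 lower genes only Chac1 passed there (limma adjusted p = 0.0331). Of the 55 genes lower with mutSOD1-ACM than with wtSOD1-ACM, 45 were also called higher with wtSOD1-ACM than in control, and 0 were called between mutSOD1-ACM and control. These comparisons share the wtSOD1-ACM libraries, so an overlap in this direction arises in part from the sharing, and it was not tested against a value for no effect.

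The fourth comparison set mutSOD1-ACM against untreated cultures. Smad7 (identifier 81516), an inhibitor of TGF-beta receptor signalling, rose from 6.67 ± 0.56 to 10.5 ± 0.78 FPKM (SD, n = 5 each; log2 fold change 0.59, limma adjusted p = 0.00232; 0.51 in set 1 and 0.70 in set 2). Pmepa1 (311676), another TGF-beta target that dampens the pathway, rose from 66.3 ± 7.96 to 98.2 ± 5.27 FPKM (0.57, limma adjusted p = 0.0316; 0.48 and 0.69). With wtSOD1-ACM they stood at 12.1 ± 0.98 and 114 ± 7.13 FPKM, and with polyP at 5.05 ± 0.45 and 51.1 ± 6.56 FPKM. The next smallest p belonged to Chac1 (50.3 ± 5.29 and 33.3 ± 4.74 FPKM, -0.59, limma adjusted p = 0.0905), Ppp1r14a (5.53 ± 1.07 and 8.46 ± 1.00 FPKM, 0.54, 0.301) and Ier5l (30.3 ± 2.90 and 38.9 ± 3.27 FPKM, 0.35, 0.301), which did not pass.

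Of the 18 TGF-beta and BMP targets 2 rose (4 adjusted over the list alone), with Id2 at 0.23 and Tgif1 at 0.21 not past the test over all genes (camera adjusted p = 5e-07, adjusted p = 0.038 with an estimated correlation, but 0.145 with the set as a term). Of 22 targets of the integrated stress response and ATF4, 0 fell over all genes and 5 adjusted over the list alone, with a median of -0.14 (camera adjusted p = 8.22e-08, adjusted p = 0.000771 with an estimated correlation). Chac1 stood at -0.59, Trib3 at -0.49, Mthfd2 at -0.24 and Aldh18a1 at -0.16. The ribosomal protein genes had a median of 0.11 with 0 of 40 past the test over all genes or over the list alone (camera adjusted p = 9.95e-12, adjusted p = 0.653 with an estimated correlation). Fos (0.03), Npas4 (-0.18), Bdnf (-0.06), Sod1 (0.13) and Gfap (-0.08) did not pass the limma test. In all, 2 genes passed, both higher, and 426 had an unadjusted p under 0.05. Set 1 alone gave 0 genes and set 2 alone 4 higher and 1 lower, and a fit of the 2 groups alone gave 0. Median-of-ratios scaling and quantile normalization each gave 1 higher gene, Smad7, and 1 lower, Chac1 (-0.60, limma adjusted p = 0.0497 and 0.0485). The call of Pmepa1 was lost there (adjusted p = 0.0786 and 0.137) and with equal summed FPKM (adjusted p = 0.102), and it ended without any of 12 single libraries (limma adjusted p of up to 0.164 without mutSOD1-ACM replicate 2).

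**Figure D3:**
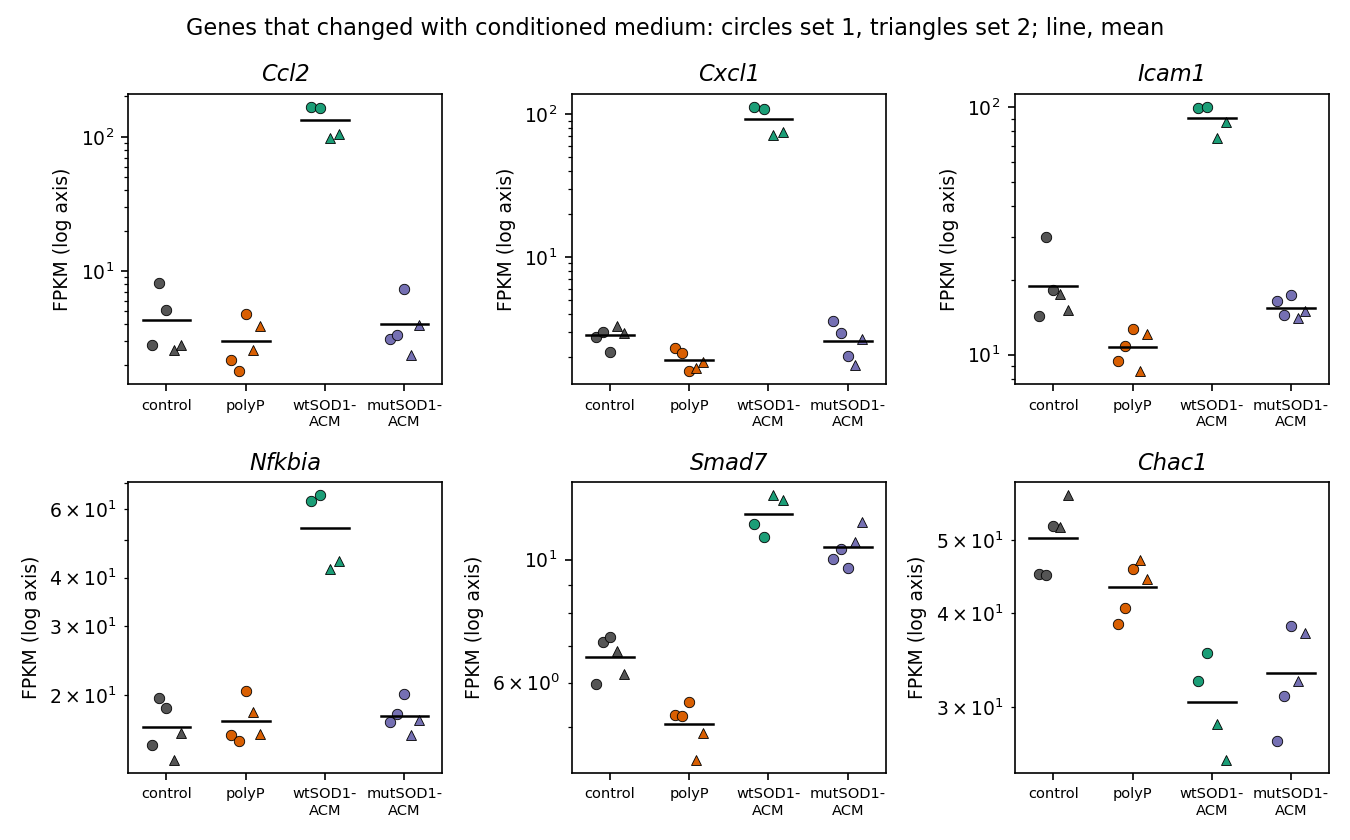
FPKM of 6 genes in the 4 groups on a logarithmic axis, each library a point (circles, set 1; triangles, set 2), with the group mean as a line. Ccl2, Cxcl1, Icam1 and Nfkbia were high with wtSOD1-ACM and near control with mutSOD1-ACM (Ccl2 134 against 4.02 FPKM, control 4.28), while Smad7 was higher than control with both media and Chac1 passed the test with wtSOD1-ACM.

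On the question of common transcripts, 0 genes were called higher both with polyP than in control and with mutSOD1-ACM than with wtSOD1-ACM (0.23 for independent lists). The calls were lower in both for 23 genes (4.83 for independent lists, one-sided Fisher's exact test adjusted p = 3.15e-10 over 20 overlaps). Among the 23 were Lif, Icam1, the integrin Itga5, the AP-1 component Fosl1, Tnfaip2, the RNA-binding protein Zfp36, the mechanosensitive channel Piezo1, the growth factor Pdgfb, the hyaluronan synthase Has2 and Nfkbiz. Lif, for example, fell by 1.43 with polyP and was lower by 1.66 with mutSOD1-ACM than with wtSOD1-ACM. It stood at 10.9 ± 1.88 FPKM with mutSOD1-ACM and 37.8 ± 12.7 FPKM with wtSOD1-ACM, against 11.6 ± 3.63 FPKM in control. Of the 23, 20 were called higher with wtSOD1-ACM than in control and 0 were called between mutSOD1-ACM and control. For these 20 the calls point to a rise with the wild-type medium, without a called fall with the mutant medium. The reverse pair, lower with polyP and higher with wtSOD1-ACM, held 30 genes (5.88 for independent lists, adjusted p = 5.53e-14), a pair that shares the control libraries. The calls of Has2 with polyP and of Pdgfb, Piezo1 and Zfp36 between the media ended without any of 11 to 14 single libraries, and the 23 became 15 without wtSOD1-ACM replicate 1, wtSOD1-ACM replicate 2 or mutSOD1-ACM replicate 1 and 14 without mutSOD1-ACM replicate 2. The absence of shared higher genes depended on the fit. With the set as a term 6 genes were higher in both (2.29 for independent lists, Fisher's exact test adjusted p = 0.0205). In that fit 36 were lower in both (17.9 for independent lists, Fisher's exact test adjusted p = 5.93e-05), a smaller excess than in the main fit. Fisher's test takes genes as independent, which they are not. The shared counts were 668 higher and 401 lower with array weights, 2 and 13 in set 1 alone, and 1 and 31 in set 2 alone. Among genes with a mean FPKM of at least 5 the overlap was 15.

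Across the 11887 genes the log2 fold changes of these 2 comparisons had a Pearson's r of 0.497 (covariance 0.0263), while simulations without effect gave a mean r of 0.044, at least as large as the observed r in 14 of 100 simulations, and a mean covariance of 0.00109, at least as large in 0. The 2 classes within set 1 were spread unequally in the same direction in both comparisons. Simulations with the effects of the classes and no other effect gave a mean r of 0.383 (as large in 29 of 100) and a mean covariance of 0.00517 (as large in 0). So r does not tell a common response from the classes. With the classes as a term r was 0.211 (as large in 37 of 100) and the covariance 0.00823 (as large in 1 of 100). Genes are not independent replicates, and the simulations hold no effect in either comparison. A real effect of polyP can widen the spread of the covariance even without a common response. The small shares for the covariance, here and against untreated cultures, therefore do not test for a common response. Against untreated cultures, 0 genes were called in the same direction with polyP and mutSOD1-ACM (0.46 higher and 0 lower for independent lists). Only 2 genes were called with mutSOD1-ACM at all. The 0, here and in the splits of the controls below, therefore says little about a common response. Smad7 and Pmepa1 were called in both but in opposite directions, higher with mutSOD1-ACM and lower with polyP (0.175 for independent lists, Fisher's exact test adjusted p = 0.0308). With the set as a term this overlap did not pass (2 genes, 0.388 for independent lists, adjusted p = 0.108). The fold changes had an r of 0.702 and a covariance of 0.0274, with 78.2% of genes of the same sign, while simulated unchanged groups against the same controls gave a mean r of 0.481 (as large in 33 of 100), a mean covariance of 0.00643 (as large in 1 of 100, and in 0 with the effects of the classes) and 66.8% (as large in 22 of 100). With the 5 controls split into 2 and 3, r was 0.215 on average over 20 splits (-0.190 to 0.598), the covariance 0.0103 (-0.016 to 0.0346) and the shared calls 0 in each.

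The direct comparison of polyP with mutSOD1-ACM shares the polyP libraries with the comparison against control, so genes in common arise in part from the sharing, and Smad7 and Pmepa1 were also called higher with mutSOD1-ACM than in control. Ptgs2 stood at 9.41 ± 1.91 with polyP and 30.4 ± 3.64 FPKM with mutSOD1-ACM (n = 5 each; log2 fold change -1.60, limma adjusted p = 4.47e-07), and Hbegf, a heparin-binding EGF-like growth factor, at 52.3 ± 10.9 and 139 ± 13.9 FPKM (-1.41, limma adjusted p = 5.64e-06). Lif (-1.38), the neuropeptide Gal (-1.29), Flnc (-1.26), Plaur (-1.25), Clcf1 (-1.23), Egr1 (-1.20), Thbs1 (-1.19) and Epha2 (-1.17) were lower with polyP. Fabp7 (0.74), the neural transcription factors Pou3f2 (0.59) and Sox2 (0.58), S100a1 (0.65), Pclaf (0.66), Hmgb2 (0.64), Psat1 (0.60) and Ddit4l2 (0.88) were higher, as were Olig1 (0.66) and the uncertain Ybx1-ps3 (0.72), whose calls ended without single libraries (limma adjusted p of up to 0.133 and 0.0908). Of 18 TGF-beta and BMP targets 9 were lower with polyP (11 adjusted over the list alone), with Smad7 (-0.93), Pmepa1 (-0.94), Id3 (-0.76) and Id2 (-0.52; camera adjusted p = 9.95e-12, adjusted p = 0.00763 with an estimated correlation, but 0.0571 with the set as a term). Of 40 ribosomal protein genes 39 were higher (40 adjusted over the list alone; camera adjusted p = 1.55e-17, adjusted p = 0.182 with an estimated correlation).

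In all, 1760 genes were higher and 582 lower with polyP than with mutSOD1-ACM. Set 1 alone gave 60 higher and 56 lower, set 2 alone 2693 and 1836, and the set term 2998 and 1289, with all 2342 genes of the same sign in both sets. With median-of-ratios scaling the calls were 742 higher and 732 lower, with equal summed FPKM 787 and 746, and after quantile normalization 1115 and 612.

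The difference between the polyP effect and the mutant medium effect, each against its own reference, was tested as an interaction. It was positive for Ccl2 (4.44, limma adjusted p = 2.62e-05), Cxcl1 (4.29), Ccl20 (2.33), Ccl7 (1.97), Icam1 (1.73) and Nfkbia (1.58, limma adjusted p = 3.82e-04), which were called higher with wtSOD1-ACM than with mutSOD1-ACM or in control. It was negative for Egr1 (-1.23, limma adjusted p = 0.00799), Ptgs2 (-1.18), Egr2 (-1.03) and Id3 (-0.87), which were low with polyP. In all, 264 genes passed as positive and 79 as negative, and 2421 had an unadjusted p under 0.05. The count depended on single libraries. Without control replicates 2, 3, 4 and 5 it was 212, 717, 43 and 533, without polyP replicates 1 to 5 92, 67, 625, 80 and 39, without wtSOD1-ACM replicates 1, 2 and 3 31, 23 and 50, and without mutSOD1-ACM replicates 3, 4 and 5 59, 41 and 42. It was 11 and 1 in set 1, 932 and 973 in set 2, and 1590 and 659 with the set as a term. The excess of positive calls depended on scaling, with 46 positive and 75 negative after median-of-ratios scaling, 70 and 87 with equal summed FPKM and 89 and 64 after quantile normalization. The calls of Birc3 (1.88), Gbp5 (1.76), Cxcl2 (1.70), Cebpd (1.51), Thbs1 (-1.21), Ltbp2 (-0.97), Arc (-0.95), Id1 (-0.93) and the uncertain Mir138-2 (-2.11) and Mir1896 (-1.23) ended without single libraries, with limma adjusted p of up to 0.105.

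**Figure D4:**
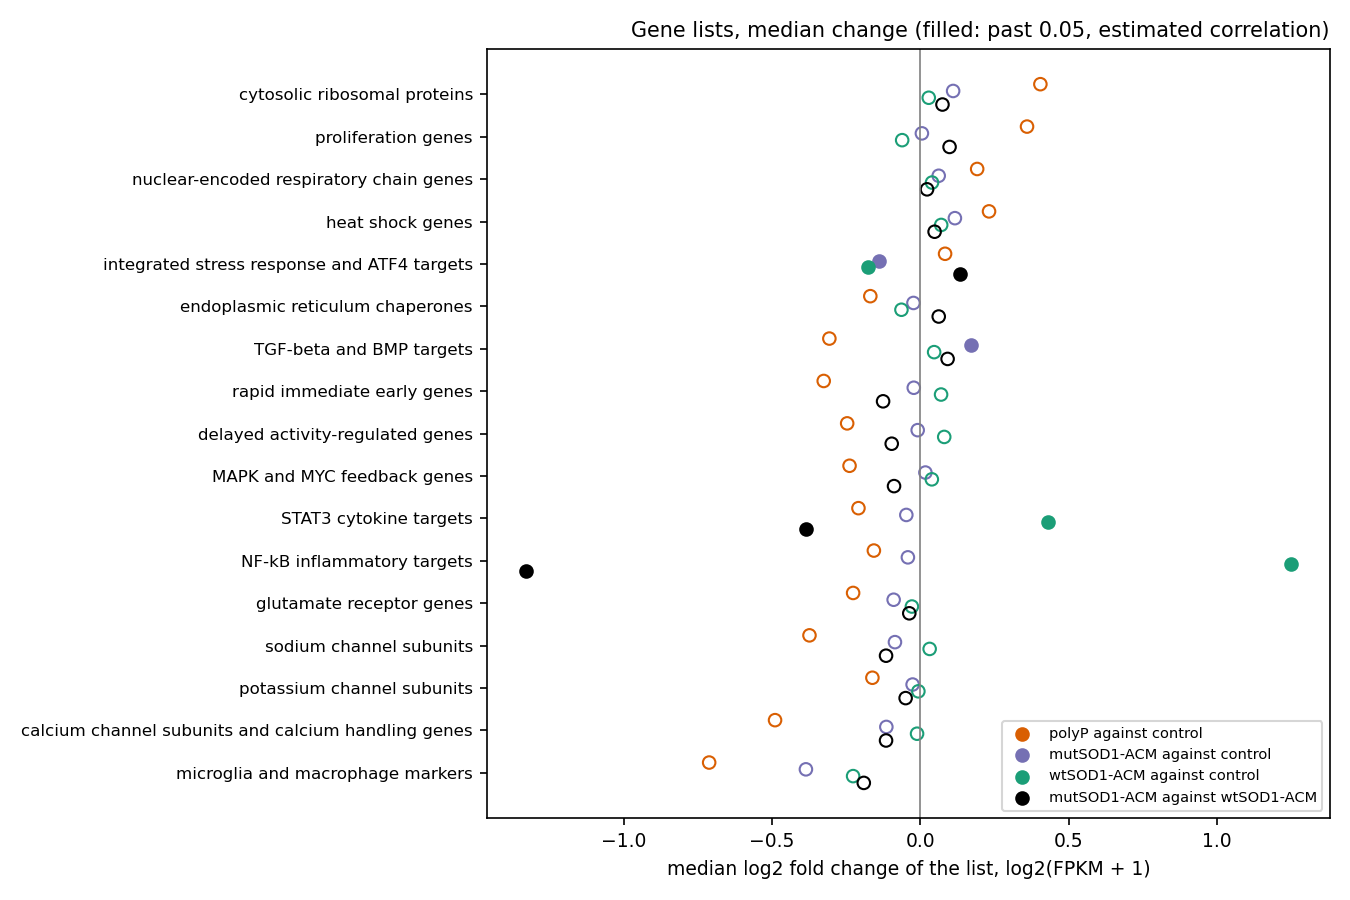
Median log2 fold change, on the log2(FPKM + 1) scale, of 17 gene lists described in the text and so chosen after the results were seen, in 4 comparisons (colours); filled circles passed camera with an estimated correlation. The NF-kB list lies at 1.25 for wtSOD1-ACM against control and -1.33 for mutSOD1-ACM against wtSOD1-ACM, and no polyP point is filled.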

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

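Chosen after the result was seen were the tests of scaling, of a single library set, of the inflammatory genes and of the library sets, while the test with summed FPKM as a term was written before its result was seen, but with a library set term that was chosen after the data were seen.

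For the genes named in the text and for library values such as summed FPKM and relative depth, 552 groups of 4 or 5 values were tested. The test looked for a library far from the others of its group (Dixon's test at its 95% critical value). In all, 30 values stood apart, where chance gives about 1 in 20 groups. The number is near that share, so the single values below are listed and not taken as effects. Microglia genes stood apart together in 2 libraries, which were the only ones of their groups in a class of library set 1 with more Mbp (328 and 332 FPKM, against 169 to 216 in the other class of the set). In mutSOD1-ACM replicate 3, Cx3cr1 was at 15.9 FPKM (others 3.33 to 6.27), Itgam at 4.44 (0.89 to 1.76) and Ptprc at 4.33 (0.96 to 1.73). The same library had Birc3 at 1.26 (0.34 to 0.55), Gbp5 at 2.21 (0.83 to 1.16) and Ahsa1 at 58.4 FPKM (66.22 to 68.84). In polyP replicate 3, Cx3cr1 was at 11.24 (2.95 to 5.19), Itgam at 2.97 (0.85 to 1.45), Flnc at 94.73 (45.86 to 53.46) and Hnrnpa1 at 645.07 FPKM (693.31 to 702.36). In control replicate 2, Icam1 was at 29.83 (14.4 to 18.22), Ccl7 at 1.68 (0.36 to 0.58) and Ltbp2 at 19.68 FPKM (10.01 to 11.29).

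The other values apart were these. Control replicate 1 had Gria2 at 30.59 FPKM (others 40.8 to 43.88), Kcnk3 at 25.6 (16.86 to 18.99) and Pgf at 4.92 (3.31 to 3.55). Control replicate 4 had Grik2 at 22.31 (19.83 to 20.38) and Scn3a at 17.01 (14.16 to 14.87), and control replicate 5 had Ier5l at 35.45 FPKM (28.35 to 29.78). PolyP replicate 1 had Cxcl3 at 0.53 (0.08 to 0.16), polyP replicate 2 had Mir760 at 7.95 (2.27 to 3.85), and polyP replicate 4 had Mir138-2 at 1.08 FPKM with the others listed at 0. In wtSOD1-ACM replicate 3, Atp2b1 was at 73.33 (76.41 to 76.88), Pgf at 12.56 (14.23 to 14.44) and Rpl22 at 226.85 FPKM (205.36 to 208.95), and replicate 4 had Mir138-2 at 1.14 FPKM with the others listed at 0. Among the other mutSOD1-ACM libraries, replicate 1 had Sqle at 121.08 (125.34 to 126.57), replicate 2 Klf2 at 15.85 (11.89 to 13.03), replicate 4 Bag3 at 13.93 (16.11 to 16.86) and replicate 5 Ctgf at 1117.51 FPKM (882.75 to 934.25). The effect of polyP and the effect of the mutant medium, each against its own reference, differed in 343 genes by the interaction test in limma. Single libraries moved this count, from 23 without wtSOD1-ACM replicate 2 to 717 without control replicate 3, with the other values in the report.

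The polyP libraries differed from control in many genes, such as Egr1 and Rpl3, and had a higher summed FPKM. Against scaling as the whole cause, 64.8% of the calls stayed called in the same direction with equal summed FPKM, 75% with median-of-ratios scaling and 83% after quantile normalization, and against a single library set, 96.8% of the genes called in set 2 and 98.9% of those called in set 1 had the same sign in the other set. Whether the excess of higher over lower calls came from scaling stays open, since 53.7% and 45.7% of calls were higher after median-of-ratios scaling and with equal summed FPKM, but 67.7% after quantile normalization. None of these scalings uses gene lengths, and a dependence on transcript length was not tested. With summed FPKM (without ribosomal protein genes) and the library set as terms, called genes kept a median of 0.382 of their log2 fold change (0.294 to 0.464 without 1 library, 240 of 3779 still called), and ribosomal protein genes kept 0.205 (0.0866 to 0.239, 3 of 40 still called), while the rapid immediate early genes kept 1.03 (0.786 to 1.18, 8 of 17 still called). With the slope fitted here, such a trend does not account for the fall of the 17 rapid immediate early genes. That slope rests on differences within groups, which in set 1 went with the 2 library classes. Control replicate 1, for example, had a summed FPKM over all genes of 475069, against 446366 and 464290 in control replicates 2 and 3. The part kept therefore does not exclude a library-wide trend with another slope. These 17 are the members called lower in these same data, and the rest of that list was not examined. For the other calls a trend and an effect of polyP cannot be told apart. That sum is made of the values tested and was higher in each polyP library (455000 or more) than in any control (453000 or less). The same limit weakens the reading for the 17.

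Inflammatory genes such as Ccl2 and Cxcl1 were high with wtSOD1-ACM and near control with mutSOD1-ACM. Against 1 library or 1 set as the cause, the lowest wtSOD1-ACM library had an NF-kB list median of 1.11 above the controls of its set. Against more microglia, the microglia markers had a median of -0.227 (-0.522 to 0.201 without 1 library), while the NF-kB list had a median of at least 1.17 without any 1 library. Against an exchange of 1 library between the media, 0 mutSOD1-ACM libraries reached the lowest wtSOD1-ACM library of their set. A response of the cultures to the wild-type medium may be considered as a hypothesis, but a difference between batches of medium and a mislabelled whole group stay open and were not tested.

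Oligodendrocyte and microglia genes such as Mbp and C1qa were higher in library set 1, whatever the treatment. Against carried-over ribosomal RNA, its shares allow other genes a log2 difference of at most 0.0281 between libraries, while the oligodendrocyte markers had a median of 2.08 (at least 2.03 without any 1 library). A lower share of neurons alone would raise the markers of other cell types alike, but the oligodendrocyte median exceeded the fibroblast median by 1.85 (at least 1.76 without any 1 library). Cultures of different age or composition may be a candidate explanation, which was not tested because the labels give neither per library.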

How the results depend on the processing

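Chosen after the data were seen were the alternatives with library sets, with each set alone and with equal summed FPKM. Over 219 pairs of a named gene and a comparison, the alternatives left 7339 values on the same side of the threshold with the same direction, made 404 miss it and 17 pass it, and turned 63 to the other sign. Counts are in the order polyP against control, mutSOD1-ACM against wtSOD1-ACM, mutSOD1-ACM against control, wtSOD1-ACM against control, polyP against mutSOD1-ACM, the interaction, genes shared with the mutant against the wild-type medium, and genes shared with the mutant medium against control. The values as reported were 3779, 56, 2, 75, 2342, 343, 23 and 0. The set term gave 6194, 99, 2, 143, 4287, 2249, 42 and 0, with 3 classes 6631, 119, 5, 239, 5413, 3804, 54 and 0, with median-of-ratios scaling 6006, 114, 5, 154, 3664, 1631, 59 and 2, and without control replicate 2 5524, 113, 2, 160, 4856, 1995, 44 and 0. Set 1 alone gave 2470, 45, 0, 55, 116, 12, 15 and 0, and set 2 alone 5480, 74, 5, 93, 4529, 1905, 32 and 1. Array weights gave 5482, 2347, 4, 214, 4011, 2437, 1069 (668 higher, 401 lower) and 2. The replicate number as a block gave 5730, 96 (11 higher, 85 lower), 5, 119, 3767, 1193, 53 (7 higher, 46 lower) and 1. The numbers followed the library sets, so the block takes up the sets in part. Libraries of the same number had an r of deviations of -0.725 to 0.791 over 27 pairs. It was 0.0681 to 0.688 between polyP and control and 0.0781 to 0.791 between mutSOD1-ACM and control. Each negative r was in a pair with wtSOD1-ACM replicate 3, a set 2 library. Of 19 libraries, 9 had their best match in another group under their own number. Whether the numbers pair cultures beyond the sets stays open. Median-of-ratios scaling gave 1474 for polyP against mutSOD1-ACM, 121 for the interaction and 1 gene shared with the mutant medium against control. Equal summed FPKM gave 1533 and 157 for the former and 1 for mutSOD1-ACM against control. Quantile normalization gave 153 and moderation without a trend 198 for the interaction. A mean FPKM of at least 5, with fewer genes tested, gave 33 for the media and 15 shared genes. No filter gave 1 for mutSOD1-ACM against control, and fits of the 2 groups alone, with fewer libraries, gave 0 there and 33 for wtSOD1-ACM against control. Lists past the threshold with an estimated correlation were 0, 3, 2 and 3 in the first 4 comparisons, against 22, 14, 12 and 17. Set 2 alone gave 9, 7 and 7 in the last 3 of these, array weights 7 and 9 in the last 2, and the set term without control replicate 2 gave 11 for wtSOD1-ACM. Without 1 library the counts ran from 3158 to 4012, 40 to 59, 1 to 2, 56 to 78, 1598 to 2658, 23 to 717, 14 to 26 and 0 to 0, and the lists from 20 to 23, 11 to 18, 8 to 18 and 11 (without control replicate 2) to 22. Values that changed sign belonged, except Hsp90ab1 with polyP (-0.0532 after quantile normalization), to genes that did not pass the test. With polyP, Fos was 0.237 with array weights and 0.1073 in set 1 (-0.1623 to 0.1017 without 1 library), Gfap 0.04436 with array weights (-0.3345 to 0.003331), and Npas4 0.3148 with array weights and 0.02891 in set 1 (-0.3902 to 0.0376). Between the media, Npas4 was -0.4314 with array weights, -0.05206 with the set term, -0.3761 in set 1, -0.05517 with the set term without control replicate 2 and -0.06835 with the set term and median-of-ratios scaling (-0.2574 to 0.47), and Fos 0.06758 with the block (-0.1892 to 0.1486). With mutSOD1-ACM against control, Fos was -0.01219 after quantile normalization, -0.2047 in set 2, -0.005599 with equal summed FPKM and -0.1105 with the set term without control replicate 2 (-0.07087 to 0.2016). Gfap there was 0.1131 with array weights, 0.01896 with 3 classes, 0.0844 in set 2 and 0.0559 with the set term without control replicate 2 (-0.2172 to 0.1093), Npas4 0.2693 with array weights and 0.02874 in set 1 (-0.3797 to 0.158), and Bdnf 0.01031 in set 1 (-0.134 to 0.02581). With wtSOD1-ACM against control, Npas4 was 0.7007 with array weights and 0.4049 in set 1 (-0.6467 to 0.08069), Sod1 -0.1137 with array weights, -0.0283 in set 1 and -0.0316 with the set term without control replicate 2 (-0.0316 to 0.09285), and Fos -0.03452 with the block, -0.1622 in set 2 and -0.01052 with the set term without control replicate 2 (-0.1086 to 0.2223). Except where fewer genes or libraries are named, the cause was not tested. Absolute depth is not known, so its limit on low FPKM could not be given.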

Other observations

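Of the tests in this part, the splits of all libraries were planned, while the splits within library sets were chosen after the result was seen and the gene groups were chosen for description after their values were seen.

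Some ALS-linked genes and neural progenitor markers rose with polyP, where 2736 of all 11887 genes rose, and their lists did not pass camera. Of 20 tested ALS-linked genes 9 rose and 0 fell (10 and 0 adjusted over the list alone; camera adjusted p = 0.0736, adjusted p = 0.479 with an estimated correlation). Among them were the RNA-binding proteins Hnrnpa1, from 529 ± 36.5 to 688 ± 24.2 FPKM (SD, n = 5 each; log2 fold change 0.38, limma adjusted p = 1.07e-04), Hnrnpa2b1 (0.27) and Tardbp, which encodes TDP-43 (0.20). Of 12 neural progenitor markers 5 rose and 0 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.0904, adjusted p = 0.238 with an estimated correlation), with the transcription factors Sox2, from 41.9 ± 8.09 to 66.1 ± 4.13 FPKM (0.66) and Pax6 (0.51) beside Fabp7. Medians of the ALS-linked genes were 0.15 in set 1 and 0.14 in set 2, and those of the progenitor markers 0.20 and 0.35.

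Genes of sterol metabolism went both ways with polyP. Srebf2, a transcription factor of sterol synthesis genes, fell from 99.9 ± 8.48 to 77.9 ± 4.40 FPKM (-0.35, limma adjusted p = 8.18e-04), and Sqle, which encodes squalene epoxidase, fell as well (-0.27). Of 22 genes 4 rose and 5 fell (5 and 6 adjusted over the list alone), with a median of 0.17 while camera pointed down (adjusted p = 0.464, adjusted p = 0.902 with an estimated correlation).

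The libraries of each comparison were split in 100 ways, the real grouping included. Under 5% of splits is taken to argue against a random grouping of the libraries, but not against an effect of the library sets or classes. For polyP against control 1 of 100 splits, the real one, gave as many genes (3779, highest other 2161), as for the 2 media (1 of 100; 56, highest other 9), polyP against mutSOD1-ACM (1 of 100; 2342, highest other 1054) and the 23 genes shared between polyP and the mutant against the wild-type medium (1 of 100; highest other 0). The last of these tests a grouping with no effect in either comparison, and not whether 2 lists of real calls overlap by chance. As large a count came in under 5% of splits for mutSOD1-ACM against control (3 of 100; 2, highest other 3308), wtSOD1-ACM against control (4 of 100; 75, highest other 3987) and the interaction (2 of 100; 343, highest other 1270). Splits with far larger counts point to a structure of the samples, since the highest other split for mutSOD1-ACM held 5 set 1 libraries of 5 in the first group and 1 in the second, and that for wtSOD1-ACM 0 of 4 and 5. For the 0 genes shared between polyP and mutSOD1-ACM against control each split is as large by construction (100 of 100; highest other 884), so nothing follows about chance. Chance was not excluded for the numbers of lists with polyP (12 of 100; 22, highest other 28), between the media (20 of 100; 14, highest other 19), with mutSOD1-ACM (57 of 100; 12, highest other 21) and with wtSOD1-ACM (13 of 100; 17, highest other 24). The other splits had medians of 14, 11, 12 and 11 lists in the same order. Many lists thus passed camera with the preset correlation in other groupings too, so its small p-values need care.

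These splits do not respect the 2 library sets, so each comparison of 2 groups was also split in the 60 ways that keep its numbers within each set. Such splits still do not keep the 3 library classes, over which the groups are unequal, and 1 of 60 is the smallest share possible. The real grouping alone gave as many genes (1 of 60) with polyP against control (3779, highest other 2393), between the media (56, highest other 9), with mutSOD1-ACM against control (2, highest other 0), with wtSOD1-ACM against control (75, highest other 36) and for polyP against mutSOD1-ACM (2342, highest other 399). The count of 2 genes with mutSOD1-ACM, Smad7 and Pmepa1, was nevertheless 0 in set 1 alone and 0 in a limma fit of the 2 groups alone, and 426 genes had an unadjusted p under 0.05.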
